A study of Rattus norvegicus with 6 samples.

How the data were processed

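RNA of the left femoral head of adult male Wistar rats, weighing 200 ± 10 g, was hybridised to 6 Affymetrix rat expression arrays, 3 of a control group and 3 of a group with steroid-induced necrosis of the femoral head. Groups and replicate numbers were taken from the sample titles. The series description states that rats of both groups received E. coli endotoxin, a bacterial product that provokes inflammation, at 20 µg/kg in 2 intraperitoneal injections 24 h apart. The experimental group then received methylprednisolone, a synthetic glucocorticoid, at 40 mg/kg in 3 injections into the gluteal muscle, again 24 h apart, and was killed 6 weeks after the steroid. The same record also calls the comparison rats normal, so it is not settled whether the control rats received endotoxin. If they did not, steroid minus control includes an effect of endotoxin. Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was made from 500 ng of it with a kit that primes from the 3' end of transcripts. The labels do not state whether each array held the RNA of 1 rat, so the p-values measure only the spread between these arrays, which may be technical in part.

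The values deposited by the authors are log2 signals, 1 for each probe set and array. Per the submitters' processing notes, RMA and Partek were used; their versions and the role of each are not given in the sources used here. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set on the log2 scale, so a difference in total RNA between arrays is removed before any test, and small differences near the background are compressed. The values were used as deposited, with no further normalization and no filter on dim probe sets. All 31042 probe sets entered the fit. The table held no probe sets of Affymetrix control transcripts, so the comparison of 3' with 5' signal that had been set out as a sign of RNA quality could not be run.

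Probe sets were named through the platform annotation, with symbols updated by Entrez gene identifier to the gene table of the rat assembly GRCr8, used for names only, where the identifier was listed there (20758 of the probe sets with 1 symbol). Of the probe sets, 20826 had 1 symbol, 436 had several and 9780 had none listed. Only those with 1 symbol were used by name. They cover 14217 genes, 4525 of them by several probe sets. Each gene was represented by its probe set with the highest mean over the 6 arrays. The build behind the array's design is not given in the sources used here, and no coordinates are printed.

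Steroid minus control was fitted for each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and p was adjusted by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05. Because small array studies often report them, probe sets with a change of at least 2-fold and an unadjusted p under 0.05 were counted too. Errors of single changes are standard errors of this fit, and levels are given as mean ± SD of 3 arrays. Before the data were examined, 28 gene lists were fixed from general knowledge of the tissue and treatment. They stand for osteoblast and bone matrix, osteocyte, osteoclast, cartilage, hypertrophic chondrocyte, adipocyte, endothelium, hypoxia, coagulation, erythroid cells, neutrophil, B cell, T and NK cell, macrophage, megakaryocyte, mast cell, skeletal muscle, fibroblast, marrow stroma, glucocorticoid receptor targets, inflammatory cytokines, interferon response, cell cycle, apoptosis, cholesterol synthesis, BMP and Wnt signalling, immediate early genes, and genes that earlier work proposed for osteonecrosis. Of the 417 measured genes on them, 21 are on more than 1 list. Lists had 9 to 30 measured genes and were tested with camera of limma, which compares the genes of a list with all other genes, at a preset correlation of 0.01. The same test with an estimated correlation between genes, and fry, which asks only whether the genes of a list move one way on balance, were run beside it. The score of a list on an array is the mean, over its genes, of the gene's deviation from its mean over the 6 arrays.

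The genes named were chosen by a rule that was fixed together with the lists. It takes up to 10 called genes per direction whose groups do not overlap, filled up with those of smallest unadjusted p among genes changed at least 2-fold, skipping uncharacterised symbols. It also takes up to 3 members of each list with the smallest p, and the osteonecrosis genes. No gene was called, so all 20 of the first kind are fill-ins. Named outside the rule, after their values were seen, are Myh1, Myl1, Acta1, Myh7, Isg15, Cd74, the MHC class II genes other than RT1-DMa, and the clock genes other than Bhlhe41.

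The fit was tested on simulated arrays with the means and spreads of the real ones. Among 31042 simulated probe sets for steroid minus control, 50 were changed at each of 4 sizes. The share recovered was 28% at a log2 change of 1, 72% at 2, 96% at 3 and 90% at 4, and 5.92% of the calls were false. With no change simulated, 0 probe sets were called and 5.33% had an unadjusted p under 0.05. In 20 simulations of the lists, 40 of 40 lists shifted by 0.5 were called in the right direction and 4 of 520 unshifted lists were called. The simulated genes were drawn independently, so this recovery does not cover genes that vary together between arrays. The changed probe sets and the lists were drawn from the brighter 50% of probe sets, so it does not cover dim ones either.

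Alternatives tried were leaving out the dimmest 50% or 25% of probe sets, quantile normalization, median centring, a variance trend, a robust variance prior, array weights, the replicate number as a block, 1 probe set per gene, the mean over the probe sets of a gene, a threshold of 0.10, and each array left out in turn. Leaving out both arrays numbered 1, and leaving out the skeletal muscle genes, were added after the data were seen. The number of arrays limits the precision: in the brighter 50% of the probe sets, the 95% interval of a change reached a median of 0.42 log2 to either side of it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.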

Results

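Gene expression of the femoral head, the rounded upper end of the thigh bone, was compared between rats with steroid-induced necrosis of that bone and control rats, to find the genes that differ between them. There were 3 arrays of the control group and 3 of the necrosis group, called the steroid group here. Each array held 31042 probe sets, with median log2 signals from 4.03 to 4.11. Any pair of arrays correlated across probe sets at r = 0.987 to 0.994, where probe sets are not independent replicates. Control 1 stood out by its limma array weight, which is lower for an array that strays from its group. It was 0.48, against 1.09 to 1.23 in the other arrays. The median change of all probe sets was -0.013 log2, and the number of arrays limits the precision of every value.

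Among the genes lower in the steroid arrays by at least 2-fold with the smallest p was Ddit4l, an inhibitor of mTOR signalling. Its log2 signal was 8.05 ± 0.24 in control and 6.67 ± 0.12 in steroid arrays (SD, n = 3 each), a change of -1.38 ± 0.14 (SE). The extracellular superoxide dismutase Sod3 differed by -1.23 ± 0.14, the mineralization phosphatase Phospho1 by -1.19 ± 0.15, and Bhlhe41, a repressor in the daily clock, by -1.47 ± 0.22. Dusp1, a MAP kinase phosphatase that glucocorticoids induce, differed by -1.13 ± 0.19. Tnfrsf11b, which encodes osteoprotegerin, a decoy receptor that restrains osteoclast formation, differed by -1.25 ± 0.23. The other genes of this kind were Meltf, Hmcn1, Colgalt2 and Zfp385b, with changes from -1.12 to -1.63.

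Several genes on the higher side belong to immune cells. The secreted phospholipase Pla2g2d had a log2 signal of 3.78 ± 0.56 in control and 5.50 ± 0.24 in steroid arrays (SD, n = 3 each), a change of 1.72 ± 0.31 (SE). The immunoglobulin light chain gene Iglc1 differed by 1.62 ± 0.36, the plasma cell gene Mzb1 by 1.31 ± 0.37, the mast cell carboxypeptidase Cpa3 by 1.31 ± 0.39 and the macrophage mannose receptor Mrc1 by 1.03 ± 0.33. RT1-DMa, a chain of the MHC class II peptide loading complex, differed by 1.03 ± 0.30. The remaining genes were Dpp4, Masp2, Slc22a3 and Ptpro, with changes from 1.01 to 1.16, though Ptpro was at 0.71 without control 2. Dimmer probe sets of Zfp385b differed by -0.11 and -0.027, and the dimmer ones of Masp2 by -0.00016 and -0.015. In each of these 20 genes all steroid arrays lay on one side of all control arrays. A choice by smallest p makes such a separation likely, so it adds no support. None passed the threshold: their adjusted p from limma lay between 0.685 and 0.688.

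**Figure D1:**
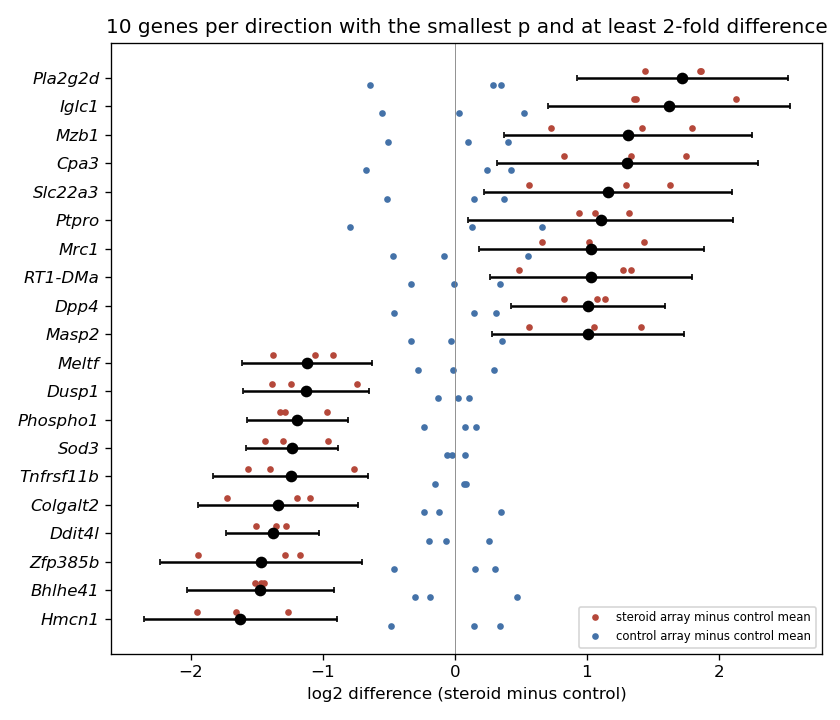
Log2 difference from the control mean for the 10 genes per direction with the smallest p among those changed at least 2-fold, with black points for steroid minus control and bars for the 95% interval. Coloured points are single arrays minus the control mean, blue for control and red for steroid, and in every gene shown the red points lie on one side of the blue points, from Pla2g2d at 1.72 down to Hmcn1 at -1.63.

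Across the array, no probe set passed an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.661. At an unadjusted p under 0.05 there were 1988 probe sets, 872 higher and 1116 lower, where 1552 were expected by chance. With 1 probe set per gene, 0 of 14217 genes passed and the smallest adjusted p was 0.685. The groups did not overlap in 5365 probe sets, 17.3% of all, where chance gives 10%. A change of at least 2-fold with an unadjusted p under 0.05 was seen in 106 probe sets, 20 higher and 86 lower in the steroid arrays. Their adjusted p lay between 0.661 and 0.712, and the groups did not overlap in all 20 of the higher and 84 of the lower ones. A separate fit with 1 probe set per gene gave 70 genes by the same limits, 15 higher and 55 lower. The count was 181 without control 3, 210 without steroid 1, 61 without steroid 2 and 315 without both arrays numbered 1, and another division of the same arrays into 3 and 3 gave 117.

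Of the 28 gene lists, 11 passed an adjusted p under 0.05 in camera with the preset correlation, 5 shifted higher and 6 lower in the steroid arrays. With an estimated correlation between genes 0 lists passed, and by fry 0 passed. There were 17 lists without control 1, and another division of the arrays into 3 and 3 gave 15. For each of the 11 lists the estimated correlation gave the highest adjusted p of all alternatives, and the lowest lay between 9.76e-18 and 0.00128. No member of any list had an adjusted p under 0.05 over all genes. Adjusted over the list alone, 1 member each passed in the immediate early, osteonecrosis, glucocorticoid and inflammatory lists, and 0 in the other 24.

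Skeletal muscle genes had the largest shift of the lists. Of 21 measured genes 20 were lower in the steroid arrays, the groups did not overlap in 16, and the median change was -1.99 log2, or 3.98-fold. The sarcomere protein Actn3, of fast fibres, had a log2 signal of 6.48 ± 1.05 in control and 3.41 ± 0.77 in steroid arrays (SD, n = 3 each), a change of -3.07 ± 0.67 (SE), and the fast troponins Tnnt3 and Tnni2 differed by -1.99 ± 0.54 and -0.80 ± 0.16, while a dimmer probe set of Tnnt3 differed by -0.0067. Myh1, a fast myosin heavy chain, was the exception at 0.031 ± 0.17, and its sign turned with quantile normalization to -0.013. Its probe set was at 11.7 log2 even in steroid 1, where Actn3 was at 2.70, so it may not report muscle. The mean over the probe sets of Myh1 differed by -0.14. The list shifted lower at an adjusted p of 2.15e-11 in camera, with adjusted p = 0.495 with an estimated correlation. Within groups these genes deviated together at a median correlation of 0.611, far above the preset 0.01. The smaller p therefore overstates the evidence for this list. Array scores were 1.34, 1.61 and 0.067 in control 1, 2 and 3, and -1.89, -0.85 and -0.28 in steroid 1, 2 and 3. The 2-fold count was 96 without these genes' probe sets.

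Genes of cartilage matrix were lower as a group: all 17 measured genes had negative changes, with a median of -0.65 log2, and the groups did not overlap in 7. Acan, the core protein of the main cartilage proteoglycan, had a log2 signal of 12.16 ± 0.39 in control and 11.18 ± 0.38 in steroid arrays (SD, n = 3 each), a change of -0.98 ± 0.28 (SE). The matrix genes Matn1 and Chad differed by -1.71 ± 0.44 and -1.03 ± 0.28. The 3 probe sets of Col2a1, the main cartilage collagen, differed by -0.23, -0.022 and -1.78, and the first of these by -0.13 without control 2 and -0.12 without steroid 2. The shift had an adjusted p of 8.74e-08 in camera and adjusted p = 0.515 with an estimated correlation. The median was -0.42 without control 2 and -0.39 without steroid 2, and muscle genes were lower in the same arrays, with a median of -1.99.

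Bone cell lists did not pass. Osteoblast and bone matrix genes had a median change of -0.17 (16 genes, 12 lower, adjusted p = 0.243), with Alpl at -0.50 ± 0.34, Sparc at -0.32 ± 0.19 and Dlx5 at -0.59 ± 0.57. The osteocyte list had a median of -0.18 over 9 genes (adjusted p = 0.568), with the phosphate regulator Phex at -0.58 ± 0.60. Osteoclast genes had a median of 0.15 over 14 genes (adjusted p = 0.570), while Car2, the carbonic anhydrase of acid secretion, was at -0.34 ± 0.10. A dimmer probe set of Car2 differed by -0.70, and which cells of the tissue gave its signal was not tested. The hypertrophic chondrocyte list had a median of -0.23 over 10 genes (adjusted p = 0.0791), with Ihh, a signal that sets the pace of growth plate maturation, at -0.89 ± 0.20 and Col10a1 at -1.08 ± 0.65. Each of these directions held with both arrays numbered 1 left out except that of the osteoclast list, which went to -0.051. Without those arrays the osteoblast, osteocyte and hypertrophic lists passed the threshold, with medians of -0.51, -0.36 and -0.66. Pth1r, Mmp13, Alpl, Ibsp and Spp1 are on both the osteoblast and hypertrophic lists as drawn up, so these lists are not independent. The osteoblast and hypertrophic lists also passed without control 1 (-0.36 and -0.51), without steroid 1 (-0.36 and -0.38), with median centring (-0.13 and -0.19) and with the dimmest 50% of probe sets left out (-0.17 and -0.23). The hypertrophic list passed too with the dimmest 25% left out (-0.23), with quantile normalization (-0.28) and with array weights (-0.37), while without control 2 the medians of these lists were 0.011 and -3.83e-05, and without steroid 2 they were 0.014 and -0.069. The osteocyte median was -0.034 without control 2, -0.060 without control 3, -0.098 without steroid 3 and -0.022 without steroid 2. The osteoclast median was 0.028 without control 1 or steroid 3, 0.058 without steroid 1 and 0.28 without steroid 2. Over the single arrays left out, Alpl ran from -0.69 to -0.22, Sparc from -0.47 to -0.15, Dlx5 from -1.13 to -0.059, Phex from -1.08 to -0.29 and Col10a1 from -1.79 to -0.67, with Dlx5 nearest 0 without steroid 2.

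Among marrow cells, erythroid genes were lower and leukocyte genes higher. All 13 erythroid genes had negative changes, with a median of -0.46 and 7 without overlap. The haemoglobin chaperone Ahsp differed by -0.47 ± 0.12, the transferrin receptor Tfrc by -0.46 ± 0.10 and the erythroid transcription factor Klf1 by -0.62 ± 0.19. The shift had an adjusted p of 1.50e-07 in camera and adjusted p = 0.495 with an estimated correlation, and muscle and cartilage genes were lower in the same arrays, with medians of -1.99 and -0.65.

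The macrophage list rose by a median of 0.65 log2, with all 12 genes higher and 5 without overlap, at an adjusted p of 1.68e-05 in camera and adjusted p = 0.466 with an estimated correlation. The complement genes C1qa and C1qc, which tissue macrophages express, differed by 0.72 ± 0.20 and 0.70 ± 0.25. In the T and NK cell list 17 of 18 genes were higher, with a median of 0.24. Its adjusted p was 0.00044 in camera and adjusted p = 0.495 with an estimated correlation. The T cell receptor component Cd3g differed by 0.80 ± 0.24. Cd8a and the NK receptor gene Klrd1 differed by 0.43 ± 0.15 and 0.16 ± 0.05 at dim mean log2 signals, 3.13 in control for each against 3.55 and 3.28 in steroid arrays, and the other probe sets of Cd8a differed by 0.010 and 0.0038. Cd8a was at 0.27 without control 3. The T and NK median was 0.16 without control 2 and 0.55 with the dimmest 50% of probe sets left out. Muscle and cartilage genes were lower in the same arrays, with medians of -1.99 and -0.65.

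Of 11 B and plasma cell genes 9 were higher, with a median of 0.49, among them Pou2af1 at 0.55 ± 0.19 and the precursor gene Vpreb3 at 0.68 ± 0.24. The adjusted p was 0.00575 in camera and adjusted p = 0.561 with an estimated correlation. The call was lost without control 3, where the median was 0.44, and the median was 0.28 without control 2, 0.74 without control 1 and 0.80 without both arrays numbered 1. Of 12 neutrophil genes 11 were higher, with a median of 0.35, while 1 had no overlap: the granule protein gene Lcn2, at 0.31 ± 0.12. Fcnb, a ficolin of granulocyte precursors, was at 1.41 ± 0.74 (0.87 without control 2) and the defensin Np4 at 0.93 ± 0.42. The neutrophil shift had an adjusted p of 0.00668 in camera and adjusted p = 0.777 with an estimated correlation. The call was lost without control 2, where the median was 0.22, and without steroid 2, where it was 0.098, and the median was 0.54 without steroid 1 and 0.63 without both arrays numbered 1. In the mast cell list 8 of 10 genes were higher, with a median of 0.45. The mast cell chymase Cma1 was at 1.29 ± 0.50 (0.74 without control 2), and Mcpt4, at dim signals of 3.47 and 3.31, at -0.16 ± 0.05. Its adjusted p was 0.0434 in camera and adjusted p = 0.495 with an estimated correlation. The call was lost without control 3, without steroid 1 and without both arrays numbered 1, where the medians were 0.56, 0.55 and 0.53, and the median was 0.30 without control 2 and 1.07 with the dimmest 50% of probe sets left out. Muscle and cartilage genes, with medians of -1.99 and -0.65, were lower in the arrays in which these leukocyte lists were higher.

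**Figure D2:**
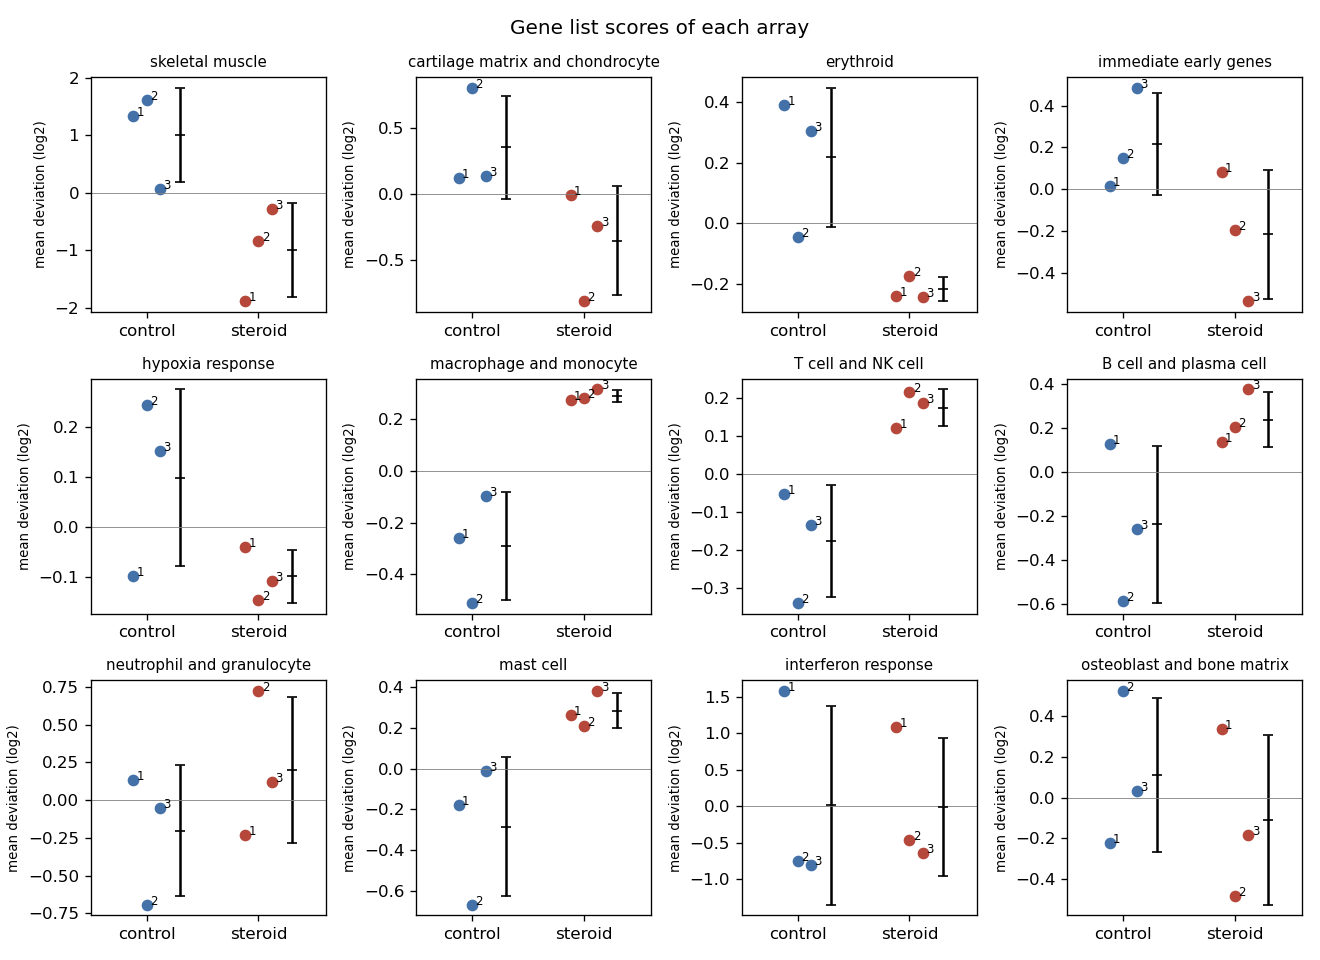
Scores of 12 gene lists on each array, as mean deviation of the list's genes from their mean over the 6 arrays in log2 units, with control arrays in blue, steroid arrays in red and their replicate numbers beside the points. Black marks show the group mean ± SD of 3 arrays. Muscle scores run from 1.61 in control 2 to -1.89 in steroid 1, and interferon scores are highest in control 1 at 1.58 and steroid 1 at 1.08.

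Immediate early genes, which respond within minutes to stress and growth signals, were lower in 14 of 17, with a median of -0.36 and 2 without overlap on the lower side. The RNA-destabilising protein gene Zfp36 differed by -0.88 ± 0.15, with adjusted p = 0.0357 in limma when adjusted over the list alone. The AP-1 genes Jun and Junb differed by -0.82 ± 0.26 and -0.86 ± 0.33. Dimmer probe sets of Jun differed by -0.51 and -0.42, with groups that overlapped. The shift had an adjusted p of 0.00044 in camera and adjusted p = 0.495 with an estimated correlation. The median was -0.18 without control 3, -0.57 without both arrays numbered 1 and -0.60 with the dimmest 50% of probe sets left out. In the same arrays the muscle and cartilage lists were lower, with medians of -1.99 and -0.65.

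Hypoxia genes shifted lower by a median of -0.13, 12 of 17 in that direction and 4 without overlap. The angiogenic factor Vegfa differed by -1.03 ± 0.28, the mitophagy gene Bnip3 by -0.76 ± 0.17 and the vasodilator gene Adm by -0.34 ± 0.11, while a dimmer probe set of Vegfa differed by -0.19. The adjusted p was 0.0203 in camera and adjusted p = 0.655 with an estimated correlation. The call was lost without control 2, where the median was -0.089, and without control 3, where it was -0.14. It was also lost with the replicate number as a block, at an adjusted p of 0.0905 in camera. The median was -0.20 without both arrays numbered 1. The arrays with lower hypoxia genes were also those with lower muscle and cartilage genes, whose medians were -1.99 and -0.65.

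Genes proposed for osteonecrosis by earlier work shifted lower at an adjusted p of 0.00225 in camera, and adjusted p = 0.495 with an estimated correlation. The median change was -0.088 and the mean -0.26, with 14 of 17 genes lower and 6 without overlap. Of these 6, Tnfrsf11b, Vegfa and Tnfsf11 had signals well above the dimmest probe sets, while Abcb1a, Il6 and Apoa1 had mean log2 signals of 2.97, 2.75 and 2.24 in control and 2.92, 2.71 and 2.21 in steroid arrays, and median centring turned the change of Apoa1 to 0.0094. Tnfrsf11b, named above, had adjusted p = 0.0474 in limma when adjusted over the list alone, and Vegfa was at -1.03 ± 0.28. Tnfsf11, which encodes the ligand that osteoprotegerin binds, was at -0.27 ± 0.16, Hif1a at -0.38 ± 0.22, Bmp2 at -0.43 ± 0.38 and A2m, which encodes a protease inhibitor of plasma, at -0.52 ± 0.43. Single arrays left out brought these to as little as -0.10 for Tnfsf11 (control 2), -0.22 for Hif1a (steroid 3), and -0.19 for Bmp2 and -0.17 for A2m (steroid 2), and to as much as -0.75 for Bmp2 (control 1) and -0.82 for A2m (steroid 3). On the higher side, the adipogenic regulator Pparg was at 0.092 ± 0.11 and the glucocorticoid receptor gene Nr3c1 at 0.017 ± 0.073, which quantile normalization turned to -0.013 and whose dimmer probe set differed by -0.25. The muscle and cartilage lists were lower in these arrays too, with medians of -1.99 and -0.65. The median was -0.045 without control 1, -0.047 with median centring and -0.054 with quantile normalization, and -0.38 and -0.22 with the dimmest 50% and 25% of probe sets left out.

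The list of glucocorticoid receptor targets did not pass, with a median of -0.012 over 16 genes (7 higher, 9 lower, adjusted p = 0.312) whose sign turned with median centring to 0.029. Its members differed in both directions, and the fry test for change in either direction gave adjusted p = 0.057 over the lists, or 0.0106 unadjusted. By that test no list passed. The macrophage, immediate early, osteonecrosis and erythroid lists had a smaller unadjusted p in it, from 0.0036 to 0.0094. Dusp1 had adjusted p = 0.027 in limma when adjusted over the list alone, Sgk1 was at -0.49 ± 0.12 and the mTOR inhibitor Ddit4 at -0.73 ± 0.26. Inflammatory cytokine genes had a median of -0.015 over 19 genes (adjusted p = 0.577), which quantile normalization turned to 0.00084 and median centring to 0.025. In that list Tnfaip3, a brake on NF-kB signalling, was at 0.54 ± 0.09, with adjusted p = 0.0276 in limma when adjusted over the list alone, and Ptgs2 was at -0.59 ± 0.24. Interferon genes had a median of -0.083 over 18 genes (adjusted p = 0.767), and passed in opposite directions without control 1 (0.82) and without steroid 1 (-0.40). The sign of the glucocorticoid median turned without control 2 (0.088) and without steroid 1 (0.029), and that of the inflammatory median without control 1 (0.0084).

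Adipocyte genes, which stand for marrow fat, had a median of 0.086 over 19 genes, 14 of them higher (adjusted p = 0.119). The fatty acid carrier Fabp4 was at 0.32 ± 0.08, Adipoq at 0.59 ± 0.25 (0.38 without control 3) and the fatty acid receptor Cd36 at -0.79 ± 0.30. Endothelial genes had a median of -0.022, a mean of 0.047 and a test direction of higher over 16 genes (adjusted p = 0.905), and the median turned to 0.019 with median centring. The endothelial receptor gene Tie1 was at 0.38 ± 0.07 and the transcription factor Sox18 at 0.86 ± 0.22. Coagulation genes had a median of -0.020 over 22 genes (adjusted p = 0.549), which median centring turned to 0.021, with the protein C receptor Procr at -0.82 ± 0.29. BMP and Wnt genes had a median of -0.11 over 30 genes (adjusted p = 0.169), with the secreted antagonists Frzb at -1.15 ± 0.36 and Grem1 at -1.07 ± 0.29. Medians of the remaining lists were 0.28 for megakaryocytes (adjusted p = 0.475), -0.20 for fibroblasts (0.257), 0.14 for the cell cycle (0.0803) and 0.080 for apoptosis (0.383). Marrow stroma had a median of 0.15 and a mean of 0.023 but a test direction of lower (adjusted p = 0.425), and cholesterol synthesis a median of 0.0016 but a mean of -0.0086 and a test direction of lower (adjusted p = 0.767). The cholesterol median was -0.029 with quantile normalization and -0.086 without control 1. Without control 1 the adipocyte, cell cycle and BMP and Wnt lists passed (0.044, 0.12 and -0.23), and the megakaryocyte and marrow stroma medians were -0.44 and -0.17. Without control 3 the megakaryocyte and cell cycle lists passed (0.62 and 0.20), and without steroid 1 the fibroblast, cell cycle and BMP and Wnt lists (-0.44, 0.20 and -0.11). Median centring also brought the fibroblast and BMP and Wnt lists past the threshold (-0.16 and -0.067), the dimmest 50% left out brought the BMP and Wnt list (-0.17) and array weights the cell cycle list (0.12). Without both arrays numbered 1, the fibroblast, cell cycle and BMP and Wnt lists passed (-0.54, 0.20 and -0.17). Other arrays left out brought some of these medians near 0. The cell cycle median was 0.0095, the apoptosis one 0.028 and the BMP and Wnt one -0.022 without control 2, and the adipocyte one was 0.015 without steroid 1 and 0.050 without control 3. The BMP and Wnt median was -0.050 without steroid 2 and -0.039 without steroid 3, the apoptosis one 0.052 without control 3, and the megakaryocyte one 0.021 without steroid 2. The coagulation median was -0.036 without steroid 3. The fibroblast median was -0.022 without control 2 and 0.043 without steroid 3, and the endothelial one 0.11 without control 2, 0.0046 without control 3 and 0.067 without steroid 2.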

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

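Leaving out both arrays numbered 1, and leaving out the muscle genes, were the tests chosen after the result was seen. No probe set passed the adjusted threshold in limma under any alternative, 0.10 included, while unadjusted p under 0.05 held for 1988. The 2-fold count of 106 was 70 with 1 probe set per gene, 315 without both arrays numbered 1 and 61 to 210 with 1 array left out. With the dimmest 50% left out, quantile normalization, median centring, variance trend, robust prior and array weights it was 98 to 138. The 11 lists became 0 with an estimated correlation and 0 by fry, which allow for genes that vary together, and 9 to 17 with 1 array left out, 17 without control 1. The percentage of 2-fold probe sets that were higher, 18.9, was 26.9 with median centring and, with 1 array left out, 9.86 without control 2, 11.5 without steroid 3 and up to 30.4 without control 3. Across all probe sets the replicate numbers showed no pairing of the arrays. Deviations of same-numbered arrays correlated at -0.14, -0.28 and -0.15, and not every array correlated best with its own number. Interferon genes were high in both arrays numbered 1, so a feature shared by arrays of the same number is not excluded. As a replicate block, the number gave 68 probe sets and 10 lists, without hypoxia (adjusted p = 0.0905; range over alternatives 0.001 to 0.655). Over all alternatives, 402 list values kept direction and side of the threshold, 30 newly passed in their direction, 31 no longer passed and 40 turned sign (1 of these, interferon without control 1, then passed), and 1500 gene values kept their sign and 25 turned; the cause was not tested. With the dimmest 50% left out, endothelium was 0.013, coagulation 0.049 and cholesterol -0.0077. Quantile normalization gave inflammatory 0.00084, cholesterol -0.029, Myh1 -0.013 and Nr3c1 -0.013. Median centring gave endothelium 0.019, coagulation 0.021, glucocorticoid 0.029, inflammatory 0.025 and Apoa1 0.0094. Array weights gave megakaryocyte -0.00049, marrow stroma -0.022, interferon 0.26, cholesterol -0.050, Nr3c1 -0.015 and Isg15 0.63. The mean over probe sets gave marrow stroma -0.13, Nr3c1 -0.12 and Myh1 -0.14. Without both arrays numbered 1, osteoclast was -0.051, megakaryocyte -0.17, marrow stroma -0.30, glucocorticoid 0.015, inflammatory 0.0052, interferon 0.11, cholesterol -0.073, Myh7 0.74, Isg15 0.45, Bmal1 -0.11, Nfil3 0.097, Npas2 -0.57 and Nr3c1 -0.059. With 1 array left out, medians ran from -0.36 to 0.014 for osteoblast, -0.090 to 0.11 for endothelium, -0.44 to 0.62 for megakaryocyte, -0.17 to 0.31 for marrow stroma, -0.12 to 0.088 for glucocorticoid, -0.028 to 0.0084 for inflammatory, -0.44 to 0.82 for interferon, -0.44 to 0.043 for fibroblast and -0.086 to 0.023 for cholesterol, and changes from -0.10 to 0.19 for Myh1, -2.78 to 0.12 for Myh7, -0.22 to 0.077 for Nfil3, -0.045 to 0.077 for Nr3c1, -0.10 to 0.71 for Bmal1, -0.28 to 0.89 for Npas2, -0.046 to 0.51 for Per1 and -1.21 to 1.504 for Isg15. The comparison of 3' with 5' signal was not run, for want of control probe sets in the table analysed.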

Other observations

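Several tests here were chosen only after the result was seen. These were the MHC class II and clock output lists against other genes, macrophage minus erythroid scores, and each clock arm alone. Muscle against cartilage, macrophage and clock scores, the whole slow fibre list, and the spread of cartilage changes were also chosen then. Quantile normalization was set before the data were seen, but its use as a test of the muscle list was chosen afterwards. Genes of MHC class II, the molecules that present antigen to helper T cells, were higher in the steroid arrays. All 8 measured genes had positive changes, with a median of 0.64 log2 and 6 without overlap. The invariant chain gene Cd74 was at 0.64 ± 0.13 (SE), RT1-Da at 0.64 ± 0.13, RT1-Bb at 0.77 ± 0.19 and the peptide loading gene RT1-DMb at 0.84 ± 0.19. Against other genes, camera of limma gave an unadjusted p = 2.01e-08, and p = 0.0432 with an estimated correlation. The list was set up after RT1-DMa had been seen among the genes with the smallest p. Macrophages and B cells express these genes, and their lists were higher in the same arrays, with medians of 0.65 and 0.49. Without RT1-DMa, 7 genes gave a median of 0.64 and p = 1.42e-07, but p = 0.0645 with an estimated correlation. An exact two-sided permutation test of the array scores gave p = 0.1, the smallest that 3 against 3 arrays allow.

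Genes of the daily clock differed too. Per3, a clock repressor, was at -0.86 ± 0.09, the clock nuclear receptor genes Nr1d2 and Nr1d1 were at -0.95 ± 0.20 and -0.90 ± 0.31, and the output regulators Hlf and Dbp at -0.94 ± 0.33 and -1.46 ± 0.55, where Dbp was at -0.86 without steroid 1. In each of these 5 genes the groups did not overlap, and their adjusted p from limma over all genes was 0.685 to 0.688. Per1 went the other way, at 0.20 ± 0.31, though at -0.046 without steroid 3. A list of 7 clock output genes that left out Bhlhe41, Dbp, Per1 and Per3, which were seen before it was made, had a median of -0.51, all 7 lower and 4 without overlap, with p = 2.64e-05 in camera and p = 0.0477 with an estimated correlation.

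The clock pattern was tested as a difference in clock phase at collection, which predicts lower output genes with higher genes of the opposite arm. The score of the 7 output genes minus that of 5 opposite-arm genes differed by -0.87 ± 0.35 (SE, steroid minus control), with an exact two-sided permutation p of 0.1, the smallest possible, and by -0.53 without steroid 1. Most of it was the output arm, at -0.64 ± 0.16: the opposite arm was at 0.24 ± 0.25 (exact permutation p = 0.5) and 0.0067 without steroid 1, with Cry1 at 0.64, Bmal1 at 0.44 and Npas2 at 0.40 but Nfil3 at -0.084 and Clock at -0.21 (-0.017 without control 2), Cry1 at 0.34 without steroid 3, and Bmal1 at -0.10 and Npas2 at -0.28 without steroid 1. Bmal1 was dim, at 2.56 to 2.68 log2 in every array but steroid 1, where it was at 4.20. Another phase, and a fall of the output genes alone, therefore cannot be told apart, and the time of collection is not in the labels. Less muscle in the steroid arrays cannot be told apart as a source either, with a slope of the clock score on the muscle score of 0.0072 over the 3 control and 0.71 over the 3 steroid arrays, and an effect of the steroid on the clock stays open and untested.

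Remaining differences in scale between the deposited arrays do not account for the lower muscle list, as its median stayed at -1.999 after quantile normalization. The authors' own normalization had already been applied, so this test cannot show what that step did. Muscle carried over at dissection in varying amounts predicts that the muscle genes deviate together within the groups. They did, with a median correlation of 0.611 between genes, against a median of 0.042 and a 95th percentile of 0.199 in 1000 random lists. Genes of 1 tissue may vary together under other causes too, so carry-over stays possible but is not singled out. The abundant muscle genes Myl1 and Acta1 had log2 signals of 10.2 and 10.0 in control 1 and 3.79 and 2.46 in steroid 1. Control 3 and steroid 3 lay much closer, at 8.15 and 7.96 against 7.78 and 7.22. No gene of the muscle list is on another of the 28. The slow fibre myosin gene Myh7 was at 9.02 in control 1 against 2.83 to 5.64 in the others. Loss of fast fibres only stays open. Of 12 slow fibre genes 10 were lower, with a median of -0.71 that rests on control 1. The score of control 1 was 1.70, against -0.54 to -0.059 in the others (exact two-sided permutation p = 0.6). The 4 slow fibre genes with a mean of at least 4 log2 had a median of -0.032, 2 of them lower. Those lower were Myh7 at -1.57 and Tnnc1 at -0.18. The other 2, Atp2a2 and Tpm3, had log2 signals of 9.96 and 12.1 in steroid 1, where Acta1 was at 2.46. Their signal need not come from muscle fibres, so the median of these 4 genes cannot decide. The steroid was injected into a gluteal muscle, and an effect of it on muscle near the hip was not tested; of the 10 splits of the 6 arrays 1, the real one at 1.99, had a median this large, the highest other was 1.86, and 10 splits are too few for a share under 0.05.

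Lower cartilage with higher leukocyte genes might reflect a lower share of cartilage in the tissue taken, which raises all marrow types alike. Macrophage and erythroid genes moved apart instead, by 1.01 ± 0.08 (SE, exact two-sided permutation p = 0.1, the smallest possible). Both lists had already been seen to shift in opposite directions, so their difference is no independent test. All 13 erythroid genes were lower, where a lower share of cartilage would raise them, which argues against that share as the whole cause. The argument is weak, as the erythroid list did not pass in camera with an estimated correlation (adjusted p = 0.495). For cartilage alone it stays open, since the SD of the members' changes, 0.34, was 2.07 times their median standard error relative to the list score, between the bounds of 1.5 for a common shift and 3 against it, which were chosen after the values were seen. Less muscle in the steroid arrays would raise the share of other tissues, yet all 17 cartilage genes and all 13 erythroid genes were lower. That argues against less muscle as the whole cause, but only weakly, since these directions had been seen before. Neither list passed in camera with an estimated correlation (adjusted p = 0.515 for cartilage and 0.495 for erythroid genes). Whether the cartilage score follows the muscle score stays open. Over the deviations of 6 arrays from their group means, these scores had Pearson r = 0.076 (exact permutation p = 0.854) and Spearman rho = 0.26 (exact permutation p = 0.658). Without control 3 and steroid 1, r was 0.85. Muscle and macrophage scores had r = -0.56 (exact permutation p = 0.312, adjusted over the 2 relations 0.625) and rho = -0.31 (exact permutation p = 0.564), with r = -0.30 without those arrays. An effect of the steroid on these tissues was not tested apart from these, and 3 of the 10 splits had a cartilage median as large as the real 0.65, with 0.68 as the highest other and too few splits for a share under 0.05.

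Interferon genes stood apart in both arrays numbered 1. Scores of that list were 1.58 in control 1 and 1.08 in steroid 1, and -0.80 to -0.47 in the other arrays. Isg15, an interferon-induced ubiquitin-like protein gene, had log2 signals of 12.5 and 11.1 in these arrays and 7.40 to 7.98 in the rest. The megakaryocyte score was -1.52 in control 1 and 1.07 in control 3.

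With 3 arrays per group there are 10 splits, too few for a share under 0.05. For probe sets past the adjusted threshold in limma the real count was 0, against 1988 at an unadjusted p under 0.05. All 10 splits reach 0 by necessity, so this comparison tells nothing about chance, and the highest other gave 1. For the 2-fold count, 2 of the 10 splits gave at least the real 106, and the highest other gave 117. For gene lists, 3 of the 10 splits gave at least the real 11, and the highest other gave 15.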
